A study of Mus musculus with 6 samples.

How the data were processed

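Polyadenylated RNA of primary RPE cells, extracted with TRIzol per the labels, was measured in 6 mouse libraries, 3 labelled Normal and 3 labelled PVR. Groups and replicate numbers were taken from the sample titles. The deposited values are a normalised signal per gene symbol: read counts that the authors had divided by 1 size factor per library before they deposited them, as shown by the values themselves. Within each library every value was a whole multiple of 1 step, and 100% of the values gave whole reads within 0.001 reads, so the reads behind each value were recovered. The deposited factors equalled the median-ratio size factors of DESeq2 recomputed over the same genes (ratio 1 in each library). Genome build mm10 and DESeq2 are named, without a role, per the submitters' processing notes, and the aligner, the counting program, its use of strand and the annotation are not given in the sources used here.

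The recovered totals were 15929388, 17075519 and 19173187 reads in Normal replicates 1 to 3 and 17507440, 15269983 and 17775427 in PVR replicates 1 to 3. At these depths the level that a count of 0 allows (3 reads) corresponds to 2.72 to 3.42 normalised counts. Such floors and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries was a duplicate, since their counts differed by a chi-square of at least 19.9 per gene. The tables hold 28043 genes, of which 27362 match a symbol of GENCODE M21 (GRCm38, the assembly also called mm10). Coordinates are from that annotation, 1-based. Of the 28043 names, 26 are dates, as a spreadsheet makes of genes named for March or September, and these hold 0.102% of the reads. They stayed in the scaling and tests but are not named. None of the 13 protein-coding mitochondrial genes was analysed here. Of the 214 genes named by the rule below or beside it, 28 share annotated exon bases with another tested gene, mostly on the opposite strand, and are uncertain to that extent (among them Serpine3 with Ints6, Mab21l1 with Nbea and Alas2 with Apex2).

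The plan written before the data were examined foresaw raw counts and edgeR as the main test, with limma on log2(value + 1) if the values proved to be normalised. They were, so the main test was limma 3.58.1 (R 4.3.3) on log2(normalised count + 1), with an intensity trend and robust moderation and no replicate block, on the 15766 genes that passed filterByExpr of edgeR on the recovered reads (minimum count 10). P-values were adjusted over all genes by Benjamini-Hochberg, with a threshold of 0.05, and an adjusted p given without another method is limma's. Count tests on the recovered reads were alternatives: the quasi-likelihood test of edgeR 4.0.16 called 4706 genes, 4682 of them shared with limma, and DESeq2 1.42.0 called 4824, 4616 of them shared, with 22 adjusted p left undefined. Both scripts and tests were tried on simulated data first. A simulation of this comparison drew 200 genes to change, with 15475 genes tested. In it limma found 2.99% of 1.5-fold, 43.3% of 2-fold and 76.9% of 4-fold changes, and 2 of its 83 calls were false. Far more genes were called in the data, which loosens the adjusted threshold, so these rates of recovery do not carry over. In the same simulation 4 of 87 calls by edgeR and 28 of 133 by DESeq2 were false. Its counts were drawn once, with dispersions estimated by edgeR and few changed genes, so these shares do not carry over either. How certain calls made by DESeq2 alone are is not known. In the list simulation 0 of 34 unchanged lists were called and the raised list was. Its genes were drawn independently, whereas members of real lists moved together (estimated correlation 0.777 in the interferon list). That simulation therefore gives no error rate for camera on these data. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

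Before the data were examined 35 gene lists were fixed (875 symbols, 848 of them in the tables): pathways of RPE function, pigment, epithelium, mesenchyme, matrix, proteases, RANK and NFATc1, osteoclast targets, TGF-beta, growth factors, cytokines, interferon, antigen presentation and complement, cell cycle, metabolism, lysosome and stress, quality lists, and markers of other cell types. Camera was run with a preset inter-gene correlation of 0.01 over the 32 lists with at least 5 tested genes, adjusted over those lists, and again with an estimated correlation, and fry was run beside it. The rule for named genes, fixed at the same time, took the 8 genes with the largest change in each direction among called genes with a mean log2 CPM of at least 3 and groups that did not overlap, without unnamed gene models. It added a fixed set (Tnfrsf11a, Tnfsf11, Tnfrsf11b, Traf6, Nfatc1, Rpe65, Acta2, Fn1 and Col1a1). Also added were up to 4 members of each list with the smallest p and the 5 genes with the smallest p of all. List members that show a list going both ways were added too. For the list members the plan named the p of edgeR, and the p of limma was used. Other members given as examples (Rlbp1, Lrat, Rgr, Enpp2, Snai1, Krt8, Col3a1, Atp6v0d2, Tgfb1, C1qa, Ptprc, Cd163, Il1b, Tnf, H2-D1, Cd74, Mki67 and Hmgcs1) and the genes Trf, Tfrc, Fth1, Ftl1, Chrna3, Arg1, Map1a, Tubb4a and Aplp1 were chosen after their values were seen. Some genes that the rule names are not reported here.

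Groups share replicate numbers, so it was checked whether the numbers pair the libraries. Deviations from the group means correlated across genes by 0.206, 0.195 and 0.179 for the same-numbered libraries 1 to 3, and by -0.0689 to -0.137 for different numbers. Within a group the deviations of a gene cancel, so positive values for the same numbers force negative ones elsewhere. By the criterion set beforehand (every pair over 0.1) the numbers were taken to pair the samples. The labels state no pairing, and what same-numbered libraries share is not known. The main test was planned without a block, so the fit with the replicate number as a block is given beside a result only where it changes the call. The alternatives fixed before the data were examined were scaling to library totals, edgeR with DESeq2 size factors, DESeq2, limma-voom with quality weights, no filter, a filter at 1 CPM, the replicate block, each library left out in turn, replicates 1 and 2 only, and a test against a 1.5-fold change. Those planned within an edgeR fit (library totals, the block and the 1.5-fold test) were run within limma, the main test. Those chosen after seeing the data were edgeR with TMM on recovered reads, TMM scaling in limma, pseudocounts of 8 and 0.25, and the fit without Normal replicate 2 and PVR replicate 3.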

Results

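RNA was sequenced from primary mouse retinal pigment epithelium (RPE) cells, the pigmented cell layer behind the photoreceptors that recycles visual pigment and takes up shed outer segments. The cells came from normal mice and from mice with proliferative vitreoretinopathy (PVR), a scarring disorder of the injured eye in which RPE cells are thought to contribute to contractile membranes. There were 3 Normal and 3 PVR libraries, and between 15269983 and 19173187 reads per library were assigned to genes. Values are normalised read counts, given as mean ± SD of the 3 libraries of a group. A log2 change is PVR minus Normal on the log2(normalised count + 1) scale, which understates the change of genes with few reads. Nothing in the sample descriptions says that the replicates were separate animals, so the p-values measure only the spread between these libraries, which may be technical. The series title places the comparison in a study of RANK and NFATc1 signalling, and the question here was which transcripts differed between RPE preparations of normal and PVR eyes.

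Among called genes with a mean log2 CPM of at least 3 and groups that did not overlap, the largest rises included Serpina3n, an acute-phase protease inhibitor (361 ± 396 to 269463 ± 62134, log2 change 10.09), Spp1, which encodes osteopontin (33.9 ± 15.0 to 12860.5 ± 6721), and complement C4b (136 ± 92.1 to 10511 ± 807). Others were the fatty-acid-binding protein gene Fabp5 (22.3 to 1736), the extracellular sulfatase gene Sulf2 (49.3 to 3664), the lysozyme gene Lyz2 (469 ± 276 to 34223 ± 18328), Serpine3 (421 to 27465) and Timp1, a metalloproteinase inhibitor (37.8 ± 25.2 to 1837 ± 932). The largest falls by the same limits included Dgkb (515 ± 27.8 to 66.6 ± 24.6), the claudin gene Cldn2 (2642 ± 199 to 387 ± 111, log2 change -2.80), and Sostdc1 (4366 to 864). Others were Pde6c (354 to 68.6), Plk5 (1960.4 to 411), Gzmm (689 to 148), the GABA transporter gene Slc6a13 (14344 to 3029) and Ermap (4549 to 940.2). The 5 smallest p-values belonged to A2m, which encodes the protease-binding protein alpha-2-macroglobulin (10142 ± 701 to 163536 ± 30281), Gnb3 (38.3 ± 8.04 to 1275 ± 173), Chil1 (3876 ± 112 to 89991 ± 21672), Sulf2 and the nicotinic receptor subunit gene Chrnb4 (517 ± 102 to 5112 ± 228). They had limma adjusted p between 1.72e-06 and 3.24e-06. Across the 15766 genes tested, 4858 changed (limma, Benjamini-Hochberg adjusted p under 0.05), of which 2825 were higher in PVR (17.9% of genes tested) and 2033 lower (12.9%). A change of at least 2-fold was seen for 1828 of the higher and 564 of the lower genes, and of at least 10-fold for 458 and 5. The 3 PVR values lay wholly above or below the 3 Normal values for 7568 genes (48.0%, against 10% by chance). Without Normal replicate 1 the number of lower genes was 1307, and a test against a minimum change of 1.5-fold called 1481 genes. Serpina3n, C4b, Lyz2 and Fabp5 belong to families with near-identical copies, so their levels are uncertain to the extent that reads were shared among copies.

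The libraries separated by condition. The first principal component of the 500 most variable genes held 88.6% of the variance and placed the 3 Normal libraries on one side and the 3 PVR libraries on the other. Pearson correlations of log2 values across genes were 0.969 to 0.979 within Normal and 0.974 to 0.977 within PVR. Genes are not independent replicates, so these coefficients describe likeness only. PVR replicate 3 lay nearer the Normal libraries (0.929 to 0.935) than PVR replicates 1 and 2 did (0.880 to 0.893). Normal replicate 2 stood apart on the second component (7.0% of variance), and 33 genes had at least 100 normalised counts and at least 10 times the level of both other Normal libraries there. With Normal replicate 2 and PVR replicate 3 left out, an alternative chosen after seeing the data, 4268 genes changed.

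**Figure D1:**
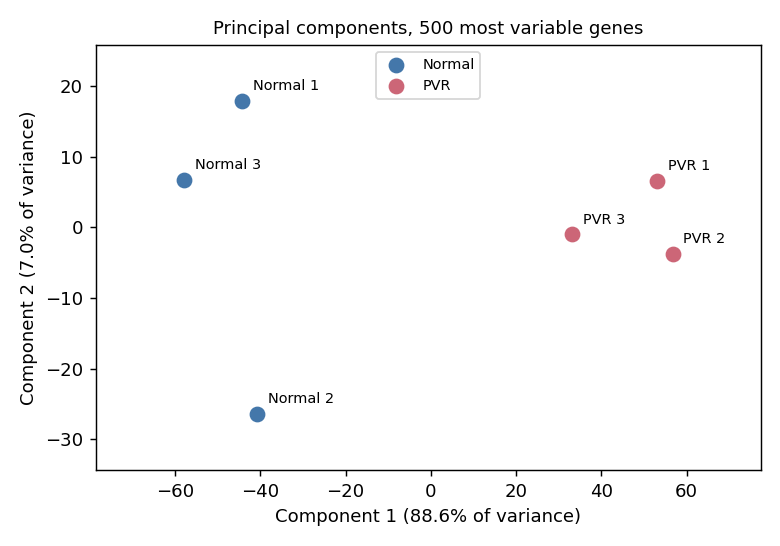
First and second principal components of log2 values of the 500 most variable genes, with 1 point per library. The 3 Normal and the 3 PVR libraries lie on opposite sides of the first component, which holds 88.6% of the variance, and PVR replicate 3 is the PVR library nearest to Normal.

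Most genes of the visual cycle and of RPE function fell in PVR. Macrophage markers rose in the same libraries by a median log2 change of 4.40 over 26 genes, and more transcripts of other cells would lower the share of RPE transcripts. Dilution alone would lower all RPE transcripts by 1 common factor. The log2 changes of this list had a median of -0.56 and quartiles of -0.90 and 0.22. Those of the melanogenesis list had a median of 0.32 and quartiles of -0.10 and 0.89. These unequal changes argue against dilution as the only cause for the 2 lists, although other cells may express some of these genes. Rpe65, the retinoid isomerase of the visual cycle (chromosome 3, 159599175 to 159625321), fell from 86793 ± 3425 to 31775 ± 5689 (log2 change -1.46, SE 0.14, limma adjusted p = 0.00012). The retinaldehyde-binding protein gene Rlbp1 fell from 89266 ± 6419 to 45597 ± 7111, the retinol acyltransferase gene Lrat from 48543 to 26022, and the RPE opsin genes Rgr from 298663 to 157350.0 and Rrh from 7766 to 3734. Enpp2, which encodes autotaxin, fell from 83980.1 ± 14424 to 21271 ± 7336 (log2 change -2.02). Of 28 tested members of the list, 18 fell and 5 rose (5 higher and 19 lower when adjusted over the list alone; camera adjusted p = 0.00326, adjusted p = 0.289 with an estimated correlation). The 5 that rose were Mfge8, a bridge protein for outer segment uptake (526 ± 56.7 to 2244 ± 413), its receptor subunit gene Itgb5 (3591 to 5411), Gas6, which encodes a ligand of the uptake receptors (2605 to 4807), Serpinf1, which encodes pigment epithelium-derived factor (320.4 to 1137), and the anion transporter gene Slc26a7 (9673 to 15451). The Slc26a7 call was lost without Normal replicate 1 (limma adjusted p = 0.056).

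Of 20 melanogenesis genes, 7 rose and 2 fell (7 higher and 2 lower when adjusted over the list alone), and the list was not called (camera adjusted p = 0.0997). It was called higher without Normal replicate 3 (camera adjusted p = 0.0445), with no filter (0.0286) and by fry (adjusted p = 0.0493). The melanosomal glycoprotein gene Gpnmb rose from 4979.6 ± 1108 to 54557 ± 9817 (log2 change 3.46), Mlana from 516 to 998 and the lysosomal channel gene Tpcn2 from 194 to 401. Otx2, an RPE transcription factor, fell from 16156 ± 864 to 10104 ± 988, and Oca2 fell from 4511 to 2660.4. The Oca2 call was lost without Normal replicate 3 (limma adjusted p = 0.051) or PVR replicate 1 (0.054). Epithelial junction and keratin genes fell more often than they rose, with 9 lower and 2 higher of 20 tested (2 higher and 10 lower when adjusted over the list alone; camera adjusted p = 0.00376, adjusted p = 0.358 with an estimated correlation). Cldn2 and Cldn7 (83.2 ± 17.4 to 17.8 ± 6.81) are tight-junction claudins that fell, the desmosomal plaque gene Dsp fell from 4083 ± 402 to 1476 ± 278 and the simple-epithelial keratin gene Krt8 from 8507 ± 1612 to 5300.3 ± 655. The 2 that rose were Cdh3, which encodes P-cadherin (4943 ± 860.4 to 10764 ± 465), and F11r (48.3 to 131). F11r lost its call without each library in turn except Normal replicate 2, without which 4 members of the list were higher. Nor was F11r called by edgeR (adjusted p = 0.0866), by limma-voom (0.0515) or by limma with no filter (0.0684). The macrophage markers rose in these libraries too.

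Mesenchymal, contractile and matrix genes rose. Acta2, which encodes smooth muscle alpha-actin (chromosome 19, 34241090 to 34255590), rose from 2337 ± 379 to 4987 ± 827 (log2 change 1.09, limma adjusted p = 0.000846), the intermediate filament gene Vim from 2446 ± 287 to 13285 ± 3533, and the tropomyosin genes Tpm1 from 699 to 1816 and Tpm4 from 313 to 1278. The transcription factor gene Snai1 rose from 21.3 ± 3.27 to 58.7 ± 11.4. Of 22 tested mesenchymal and contractile genes, 16 rose and 3 fell (17 higher and 3 lower when adjusted over the list alone; camera adjusted p = 5.09e-05, adjusted p = 0.34 with an estimated correlation). The 3 that fell were Fap (6765 ± 290.3 to 4029 ± 464), Cnn2 (1429 to 1114) and Lmod1 (642 to 383), and 1 of them remained called without Normal replicate 3. Lmod1 also lost its call without Normal replicate 1 (limma adjusted p = 0.0739) or 2 (0.0527). Among 40 collagen and matrix genes, 31 rose and 2 fell (33 higher and 4 lower when adjusted over the list alone; camera adjusted p = 6.75e-13, adjusted p = 0.276 with an estimated correlation). Fn1, which encodes fibronectin (chromosome 1, 71585520 to 71653200), rose from 366 ± 125 to 6171 ± 2227 (log2 change 4.07, limma adjusted p = 0.000912) and Col1a1 (chromosome 11, 94936224 to 94953042) from 699.8 ± 112 to 6769 ± 1815 (log2 change 3.25, limma adjusted p = 5.54e-05). Col3a1 (597 to 4102), the tenascin gene Tnc (140.3 to 1572), the periostin gene Postn (24.1 to 359.8) and the biglycan gene Bgn (1068 to 5244) also rose. Col8a2 (51874 to 34059) and the collagen chaperone gene Serpinh1 (9243 ± 3485 to 4526 ± 147) fell, but neither kept its call without Normal replicate 1 or 3, and Serpinh1 also lost it without any single PVR library. Of 30 matrix protease and inhibitor genes, 21 rose and 1 fell (22 higher and 1 lower when adjusted over the list alone; camera adjusted p = 2.04e-08, adjusted p = 0.276 with an estimated correlation). Timp1, the stromelysin gene Mmp3 (16.1 ± 4.84 to 452 ± 166), the membrane-type metalloproteinase gene Mmp14 (385 ± 27.8 to 1536 ± 246) and Adam12 (2.22 to 81.3) rose, whereas Timp3 fell from 88719 ± 10870.1 to 55285 ± 6492. Without PVR replicate 3, 2 members of that list fell. Macrophage markers rose in the same libraries, by a median log2 change of 4.40 over 26 genes. So did 10 of 19 fibroblast and stromal markers and 4 of 13 pericyte and smooth muscle markers, and these cell types also express collagens and Acta2.

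Tnfrsf11a, the gene for the receptor RANK that the study's title names (chromosome 1, 105780718 to 105847981 on GRCm38), rose from 6.85 ± 4.28 to 93.3 ± 46.6 (log2 change 3.60, SE 0.49, limma adjusted p = 0.000654). These values rest on 4, 5 and 13 reads in Normal and 79, 127 and 57 reads in PVR. Nfatc1, a calcium-responsive transcription factor downstream of RANK (chromosome 18, 80606205 to 80713071), rose from 346 ± 44.5 to 609.9 ± 139.5 (log2 change 0.80, SE 0.18, limma adjusted p = 0.00865). Tnfrsf11b, the gene for the decoy receptor osteoprotegerin (chromosome 15, 54250619 to 54278484), rose from 309 ± 35.4 to 489 ± 50.8 (log2 change 0.66, limma adjusted p = 0.00573). Tnfsf11, which encodes the ligand RANKL, had 0 reads in each Normal library and 1, 8 and 10 reads in PVR replicates 1 to 3, too few to be tested. Its PVR mean of 6.53 ± 4.77 was 2.28 times the level of 3 reads per library that a count of 0 allows (2.86). That ratio takes the PVR mean as exact, and PVR replicate 1 lay below that level (1.03), so no sure rise follows. The adaptor gene Traf6 did not pass the test (692 ± 55.5 to 721 ± 43.6, log2 change 0.06, limma adjusted p = 0.715), and its sign turned under scaling to library totals. Nfatc2 rose from 43.4 ± 11.5 to 157 ± 52.0 and the calcineurin regulator gene Rcan2 from 59.1 ± 13.6 to 152 ± 10.4. Of 29 tested genes of the RANK and NFATc1 pathway, 10 rose and 3 fell (11 higher and 4 lower when adjusted over the list alone), and the list was not called (camera adjusted p = 0.0686). It was called higher without Normal replicate 3 (camera adjusted p = 0.0494), without PVR replicate 1 (0.0451) or 3 (0.0482), with replicates 1 and 2 only (0.0421) and with no filter (0.00956). Fry also called it higher (adjusted p = 0.0431), whereas camera with an estimated correlation did not (adjusted p = 0.506). The 3 that fell were Nfat5 (4907 ± 317 to 3332 ± 185), the calcineurin subunit gene Ppp3cc (1009.9 to 728) and Src (2962 to 1908). Without Normal replicate 2, 5 members fell.

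A list of genes known as NFATc1 targets in osteoclasts was tested separately. Of its 16 tested members, 10 rose and 1 fell (10 higher and 1 lower when adjusted over the list alone; camera adjusted p = 4.87e-05, adjusted p = 0.276 with an estimated correlation). The proton pump subunit genes Atp6v0d2 (7.61 ± 7.05 to 435 ± 259) and Tcirg1 (234 ± 28.1 to 1776 ± 570.2), the protease genes Ctsk (191 ± 36.2 to 602 ± 62.9) and Mmp9 (7.70 ± 2.87 to 144 ± 88.9) and Ubash3b (56.5 to 207) rose. The anion exchanger gene Slc4a2 fell (18191 ± 1258 to 14279 ± 1370.5, limma adjusted p = 0.044), a call that was lost without any single library other than PVR replicate 3. In the same PVR libraries the macrophage markers rose, as given with the immune genes, and osteoclasts and macrophages share a lineage.

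**Figure D2:**
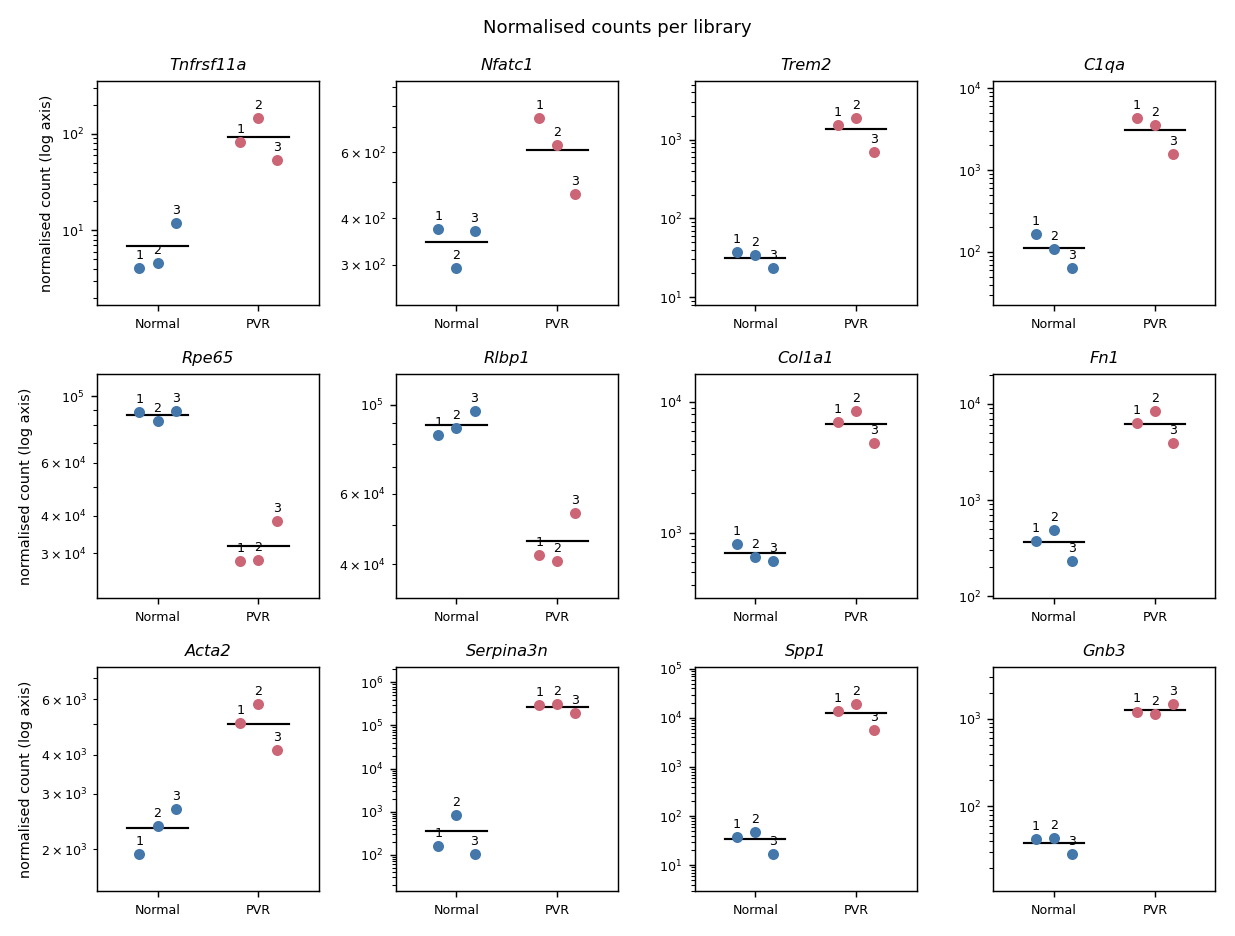
Normalised read counts on log axes of 12 genes in each Normal and PVR library, with replicate numbers beside the points and the group mean as a horizontal line. All 3 PVR values lie above all 3 Normal values for every gene shown except Rpe65 and Rlbp1, where they lie below, and PVR replicate 3 is the PVR library nearest to Normal for each gene except Gnb3.

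In the TGF-beta pathway list 15 of 28 genes rose and 1 fell (17 higher and 1 lower when adjusted over the list alone; camera adjusted p = 4.13e-07, adjusted p = 0.276 with an estimated correlation). With the replicate number as a block, 2 fell. Tgfb1 rose from 76.6 ± 14.6 to 775 ± 337 and Tgfb3 from 189 ± 42.1 to 498 ± 26.1. The activin subunit gene Inhba rose from 6.97 ± 2.23 to 109 ± 42.9, and the TGF-beta target genes Ccn2 from 1130.3 ± 74.6 to 3326 ± 257 and Pmepa1 from 483 ± 72.8 to 2372 ± 484. The co-receptor gene Tgfbr3 fell from 3725 ± 368 to 2723 ± 417, a call lost without Normal replicate 2 or 3 or PVR replicate 1 or 2. Of 27 growth factor and receptor genes long studied in PVR, 13 rose and 4 fell (14 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.0402, adjusted p = 0.276 with an estimated correlation), and 7 rose without PVR replicate 1. The camera call was lost without PVR replicate 3 (adjusted p = 0.0525) and with a filter at 1 CPM (0.0615). Pdgfra, the alpha receptor for platelet-derived growth factor, rose from 128 ± 36.0 to 442 ± 36.7, Hgf from 3.74 ± 1.46 to 78.7 ± 5.39 and Hbegf from 107 ± 25.6 to 468 ± 182. Vegfa fell from 17511 ± 3465 to 7893 ± 856 (log2 change -1.14), as did Pdgfa (1644 to 992), Fgfr2 (7362 to 5454) and Vegfc (409.6 to 282). The Vegfc call was lost without Normal replicate 1 or 3 or PVR replicate 1. In these libraries 24 of 26 macrophage markers rose, by a median log2 change of 4.40 over the list.

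Markers of macrophages and microglia showed the largest shift of any list. Of 26 tested, 24 rose and 1 fell (25 higher and 1 lower when adjusted over the list alone; camera adjusted p = 1.37e-15, adjusted p = 0.276 with an estimated correlation), with a median log2 change of 4.40. The median marker level was 42.3, 35.7 and 23.6 normalised counts in Normal replicates 1 to 3 and 941, 1207 and 460.0 in PVR replicates 1 to 3. Trem2 rose from 31.6 ± 7.14 to 1365 ± 598, Itgam from 3.87 ± 2.58 to 248 ± 98.3, the complement gene C1qa from 113 ± 51.5 to 3121 ± 1392 and Ptprc, which encodes the leukocyte antigen CD45, from 32.2 ± 10.2 to 628 ± 276. Csf1r, the receptor gene for macrophage colony-stimulating factor, was at 10038 ± 998 in Normal and fell to 7392 ± 947 (limma adjusted p = 0.0255), a call lost without Normal replicate 3 (0.086) or PVR replicate 1 (0.094) or 2 (0.053). Cd163 was at 28.6 ± 8.58 and 67.2 ± 36.3 and did not pass the test (limma adjusted p = 0.0737, 0.031 with the replicate number as a block). It passed with DESeq2 (adjusted p = 0.0384), without PVR replicate 3 (limma adjusted p = 0.0221) and without that library and Normal replicate 2 (0.0331). Only 6 of 15 listed neutrophil markers passed the filter. All 6 rose (6 higher and 0 lower when adjusted over the list alone; camera adjusted p = 9.6e-05, adjusted p = 0.276 with an estimated correlation). Among them were Csf3r (14.4 ± 6.24 to 263 ± 120.2), Trem1 (3.12 to 137), Mmp8 (0.309 to 28.0) and S100a9 (3.29 to 38.7). Only 4 of 20 listed lymphocyte markers passed the filter. Of these 3 rose and 0 fell (3 higher and 0 lower when adjusted over the list alone): Il7r (3.50 to 78.1), the immunoglobulin gene Ighm (6.08 to 30.9) and Cd4 (10.6 to 36.4). Cd4 lost its call without Normal replicate 3 or PVR replicate 1 or 2. With no filter 5 of the 20 rose, and camera called the list higher (adjusted p = 0.000168). A marker near 0 in Normal passes the filter only if it is higher in PVR. The filter therefore partly sets these counts of neutrophil and lymphocyte markers. Jchain was at 11.9 and 9.31 (limma adjusted p = 0.654).

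Inflammatory genes rose in the same libraries. Of 31 cytokine, chemokine and NF-kB response genes, 26 rose and 0 fell (31 higher and 0 lower when adjusted over the list alone; camera adjusted p = 6.75e-13, adjusted p = 0.313 with an estimated correlation). The siderophore-binding gene Lcn2 rose from 3.45 ± 2.63 to 477 ± 149, the macrophage growth factor gene Csf1 from 159 ± 11.5 to 632 ± 165 and the neutrophil chemoattractant gene Cxcl5 by a log2 change of 4.63. Il1b (38.6 ± 35.4 to 314 ± 266, limma adjusted p = 0.0834) and Tnf (23.0 ± 13.7 to 517 ± 634, limma adjusted p = 0.0549) varied widely within PVR and did not pass the test. With the replicate number as a block their adjusted p were 0.000824 and 0.000556, and Tnf also passed without PVR replicate 1 (0.029) or 3 (0.032). DESeq2 called both (adjusted p = 0.0256 and 0.000633). Tnf passed with a filter at 1 CPM (limma adjusted p = 0.0462) and a pseudocount of 0.25 (0.046) as well. The remaining alternatives called neither. In the antigen presentation and complement list 22 of 25 genes rose and 1 fell (22 higher and 1 lower when adjusted over the list alone; camera adjusted p = 1.02e-10, adjusted p = 0.276 with an estimated correlation). Cfi, which encodes complement factor I, rose from 6.29 ± 4.19 to 661 ± 74.6, the class I gene H2-D1 from 740.0 ± 142 to 8616 ± 2853 and the class II chaperone gene Cd74 from 315 ± 124 to 2017 ± 502. Nlrc5, a regulator of class I genes, rose from 20.1 to 277, and the complement protease genes C1ra from 155 to 625 and C1s1 from 173 to 574. Of 31 interferon-response genes 11 rose and 0 fell (12 higher and 0 lower when adjusted over the list alone; camera adjusted p = 7.17e-06, adjusted p = 0.506 with an estimated correlation), and 6 rose without Normal replicate 3. Fry did not call this list (adjusted p = 0.0850). Its median level was 121, 107 and 84.3 normalised counts in Normal replicates 1 to 3 and 430.4 in PVR replicate 1, against 151 and 157 in PVR replicates 2 and 3. Examples were Oas1a (3.52 to 103), Oas3 (1.34 to 90.2), Zbp1 (5.75 to 65.8) and Oasl1 (16.3 ± 9.32 to 179 ± 155). H2-D1, the Oas genes, C1ra and C1s1 have close paralogs, so their separate levels are uncertain. The median macrophage marker rose by 4.40 on the log2 scale in these libraries. Relative to the other 2 PVR libraries, the change in PVR replicates 1, 2 and 3 was a median 2.16, 0.917 and 0.345 for cytokines and 1.53, 0.782 and 0.75 for antigen presentation and complement genes. For macrophage markers it was 1.19, 1.6 and 0.387.

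**Figure D3:**
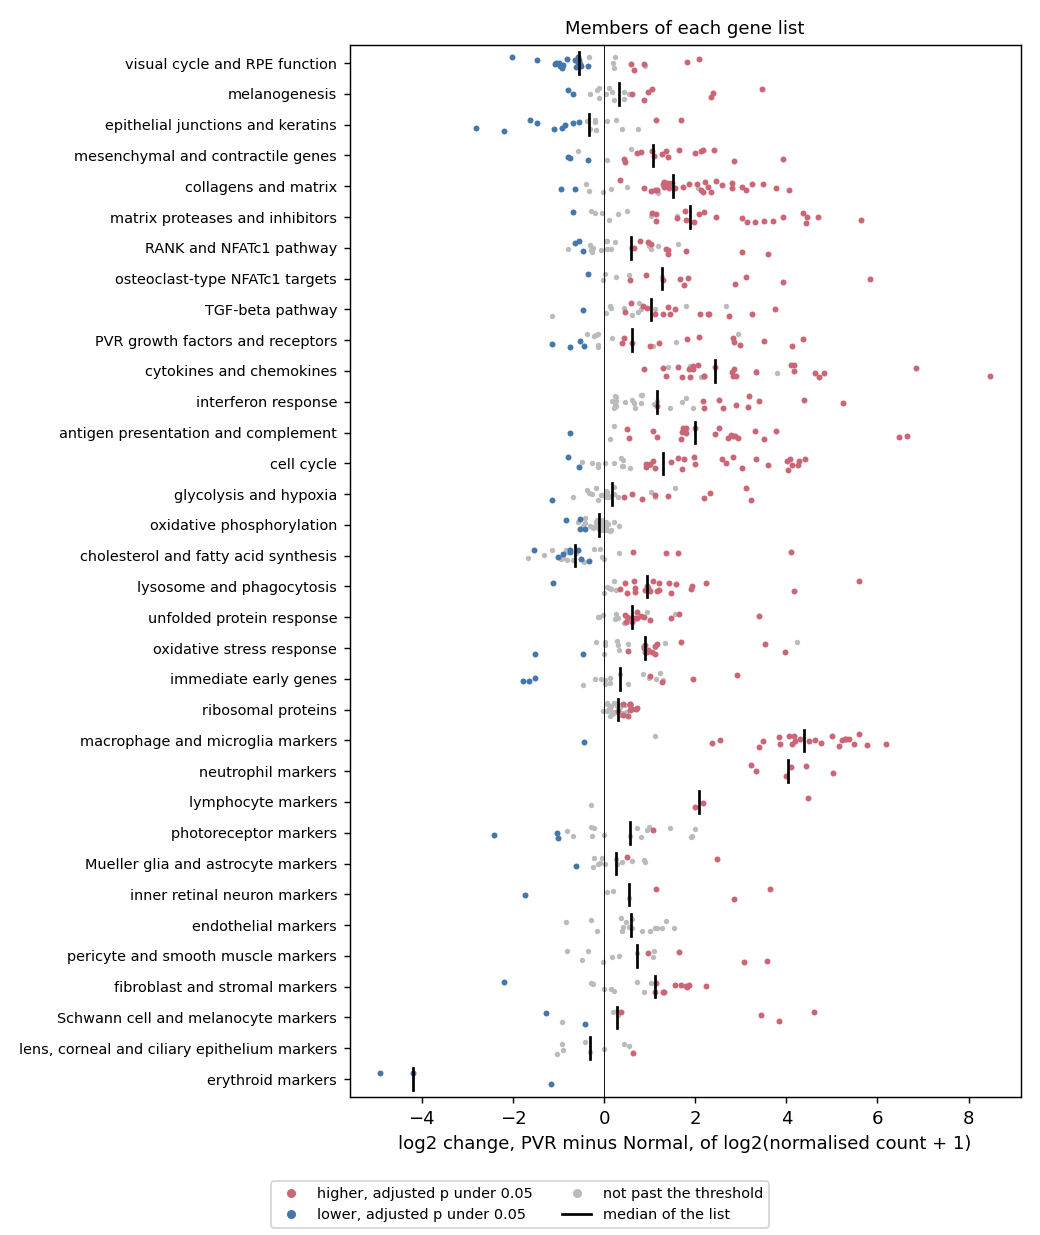
Log2 change between PVR and Normal of each tested member of the 34 gene lists with at least 3 tested genes, with the list median as a vertical bar. Red points rose and blue points fell (limma adjusted p under 0.05), grey points did not pass, and macrophage and neutrophil markers lie farthest to the right.

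Cell cycle genes rose. Of 38 tested, 24 rose and 2 fell (26 higher and 3 lower when adjusted over the list alone; camera adjusted p = 2.74e-07, adjusted p = 0.343 with an estimated correlation). The proliferation marker gene Mki67 rose from 21.3 ± 13.1 to 343 ± 162, the topoisomerase gene Top2a from 11.4 ± 3.02 to 275 ± 137 and the centromere gene Cenpa from 10.9 ± 5.10 to 184 ± 45.2. The ribonucleotide reductase gene Rrm2 rose from 13.4 to 158 and the replication helicase gene Mcm3 from 41.4 to 169. Ccnd1, which encodes the G1 cyclin D1, fell from 4979.6 ± 294 to 2879.8 ± 389, and Cdk1 fell from 323 ± 26.6 to 224 ± 37.9. The Cdk1 call was lost without Normal replicate 1 or 3 or PVR replicate 1 or 2. Relative to the other 2 PVR libraries, the change of cell cycle genes was a median 0.615, 2.12 and 0.613 in PVR replicates 1, 2 and 3. For macrophage markers it was 1.19, 1.6 and 0.387.

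Metabolic lists gave mixed results. Of 30 glycolysis and hypoxia genes 9 rose and 1, Vegfa, fell (11 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.0419, adjusted p = 0.384 with an estimated correlation). Ldha, which encodes a lactate dehydrogenase subunit, rose from 1533 ± 251 to 3324 ± 345, the lactate transporter gene Slc16a3 from 18.5 ± 8.04 to 168 ± 72.3 and Adm from 17.6 ± 5.03 to 177 ± 67.6. Without PVR replicate 1 or 3, 2 members fell. The camera call was lost without Normal replicate 1 (adjusted p = 0.0772), without PVR replicate 1 (0.0587) or 3 (0.0581) and with library totals (0.0554). Among 36 nuclear genes of oxidative phosphorylation 0 rose and 4 fell (1 when adjusted over the list alone; camera adjusted p = 0.0498, adjusted p = 0.558 with an estimated correlation). The 4 were Ndufa4 (3303 ± 207 to 2283 ± 119), Ndufb10 (1513 to 1058), Ndufs3 (1173 to 882) and Ndufb3 (999.9 to 583). That number was 2 without Normal replicate 1, 2 or 3 and 8 without PVR replicate 1. The camera call was lost without Normal replicate 3 (adjusted p = 0.101), without PVR replicate 2 (0.154) or 3 (0.0525), with replicates 1 and 2 only (0.117), with a filter at 1 CPM (0.0615) and with a pseudocount of 0.25 (0.0506). Fry did not call it (adjusted p = 0.167). Of 28 cholesterol and fatty acid synthesis genes 8 fell and 4 rose (4 higher and 8 lower when adjusted over the list alone; camera adjusted p = 0.0131, adjusted p = 0.506 with an estimated correlation), and 14 fell without Normal replicate 2. The camera call was lost with replicates 1 and 2 only (adjusted p = 0.0617), and fry did not call the list (0.137). The fatty acid elongase gene Elovl6 fell from 2099 ± 12.7 to 1051 ± 101. Hmgcs1 was at 4497 ± 3629 and 1629 ± 135 and did not pass (limma adjusted p = 0.216, 0.044 without Normal replicate 2). The 4 that rose were the cholesterol exporter genes Abca1 (4249 ± 289.9 to 11061 ± 2119) and Abcg1 (19.0 ± 11.4 to 314 ± 82.6), the desaturase gene Scd1 (293 to 907) and the transcription factor gene Srebf1 (6899.6 to 10642). Lysosome and phagocytosis genes rose together, with 22 higher and 1 lower of 29 (23 higher and 1 lower when adjusted over the list alone; camera adjusted p = 1.47e-09, adjusted p = 0.289 with an estimated correlation). The cathepsin genes Ctsb (17586 ± 1185 to 67246 ± 12947) and Ctsd (41729.5 ± 7280.3 to 158346 ± 25476) and the membrane protein gene Scarb2 (1489 to 3445) rose, and the scavenger receptor gene Scarb1 fell from 3539 ± 492 to 1641 ± 343. Macrophages are rich in lysosomal transcripts, and their markers rose by a median log2 change of 4.40 here.

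Macrophage markers (median log2 change 4.40, 24 of 26 higher) also rose in the libraries where stress-response genes did. In the unfolded protein response list 14 of 26 genes rose and 0 fell (16 higher and 0 lower when adjusted over the list alone; camera adjusted p = 3.35e-06, adjusted p = 0.343 with an estimated correlation), with 1 lower without Normal replicate 2. Sdf2l1 rose from 254 ± 6.18 to 710.1 ± 149, Hyou1 from 2299 ± 21.4 to 4051 ± 273, Edem1 from 334 to 1084 and the asparagine synthetase gene Asns from 3.12 to 42.8. Of 27 oxidative stress genes 13 rose and 2 fell (16 higher and 2 lower when adjusted over the list alone; camera adjusted p = 9.6e-05, adjusted p = 0.276 with an estimated correlation). Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1, rose from 1023 ± 323 to 11669.6 ± 2821, Gpx4 from 23165 ± 930.0 to 45352 ± 4164, Gpx1 from 1370.1 to 2979.8 and Gstm1 from 372 to 848, whereas the quinone reductase gene Nqo1 fell from 3101 ± 348 to 1115 ± 406 and Sod1 from 4896 to 3589.8. The Sod1 call was lost without any single Normal library or PVR replicate 2. Of 21 immediate early genes 4 rose and 3 fell (4 higher and 3 lower when adjusted over the list alone), and the list was not called (camera adjusted p = 0.324). It was called higher without Normal replicate 1 (0.0499), and its direction turned down, uncalled, without Normal replicate 2 (0.161). The median level of the list was 5028, 1035 and 6320 in Normal replicates 1 to 3 and 6131, 3153 and 3518 in PVR replicates 1 to 3. Nr4a2 (172 ± 46.2 to 666 ± 172), Dusp2 (12.5 to 102), Egr3 (116 to 288) and Ier3 (494 to 1009) rose, and the heat shock genes Hspa1a (36080.4 ± 8270.1 to 11703 ± 3799), Hspa1b (56070.2 ± 15393 to 19501 ± 5423) and Dnajb1 (24034 to 6619) fell. Hspa1a and Hspa1b are near-identical copies, so their separate levels are uncertain. Ier3 lost its call without PVR replicate 2 and Dnajb1 without PVR replicate 1 or 2, and 8 members were lower without Normal replicate 2. Of 38 ribosomal protein genes 11 rose and 0 fell (11 higher and 0 lower when adjusted over the list alone; camera adjusted p = 9.6e-05, adjusted p = 0.506 with an estimated correlation), by a median log2 change of 0.30. Examples were Rplp0 from 3387 to 5526, Rpl10 from 2882 to 4282 and Rps6 from 2647 to 3939. That number was 6 without Normal replicate 1, 7 without PVR replicate 1 or 2 and 18 without PVR replicate 3. Fry did not call this list (adjusted p = 0.118).

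Markers of other cell types of the eye moved far less than those of macrophages. Of 18 endothelial markers 0 rose and 0 fell by limma, and 3 and 0 at an unadjusted p under 0.05. The number that rose was 2 with the replicate number as a block, 1 with DESeq2, 0 with edgeR, 1 without Normal replicate 1 and 3 without Normal replicate 2 (camera adjusted p = 0.153). Without Normal replicate 2 camera called the list higher (adjusted p = 0.00518). Eng was at 136 ± 78.4 and 263 ± 40.6 (limma adjusted p = 0.112, 0.011 without Normal replicate 2). Of 19 fibroblast and stromal markers 10 rose and 1 fell (10 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.0086, adjusted p = 0.506 with an estimated correlation), and 6 rose without PVR replicate 1 and 4 without PVR replicate 2. Fry did not call this list (adjusted p = 0.0771). Lum rose from 73.8 ± 27.0 to 338 ± 73.4 and Mfap5 from 104 to 253, and Igf2 fell from 216 ± 49.2 to 46.2 ± 10.7. Of 13 pericyte and smooth muscle markers 4 rose and 0 fell (4 higher and 0 lower when adjusted over the list alone; camera adjusted p = 0.0963), namely Mcam (44.7 ± 18.3 to 365 ± 55.1), Anpep (75.9 to 868), Rgs5 (622 to 1195) and Des (6.62 to 22.4). Without PVR replicate 3, and with the replicate number as a block, 2 fell, and 2 were lower at an unadjusted p under 0.05. Camera called this list higher without Normal replicate 2 (adjusted p = 0.0192) or PVR replicate 2 (0.0428). Among fits without 1 library, Des kept its call only without Normal replicate 2 or PVR replicate 2. Of 19 photoreceptor markers 1 rose and 3 fell (1 higher and 3 lower when adjusted over the list alone; camera adjusted p = 0.789), with a median log2 change of 0.57 although camera pointed down. Rom1 fell from 4118 ± 490.1 to 2063 ± 503, Cngb1 from 441 to 219 and Pde6c as above. The number that rose was 5 without Normal replicate 2 and 5 with the replicate number as a block, and 0 without Normal replicate 1 or 3 or PVR replicate 2 or 3. Of 15 Müller glia and astrocyte markers 2 rose and 1 fell (1 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.626), Clu from 127450.0 to 180821, Dkk3 from 1771 ± 1598 to 7595 ± 898 and, downward, Car14 from 20117 to 13199. Dkk3 was not called with the replicate number as a block (limma adjusted p = 0.098) or by edgeR (0.083), and was called without Normal replicate 2 alone of the single libraries. Clu was not called without Normal replicate 1 or 2.

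The remaining cell type lists were short. Of 7 inner retinal neuron markers 3 rose and 1 fell (3 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.13), with Stmn2 from 3.82 ± 0.99 to 62.5 ± 31.7, Thy1 from 31.3 to 213, Rbpms from 100.3 to 221 and, downward, Syt1 from 1160.0 ± 85.5 to 356 ± 112. Fry called this list higher (adjusted p = 0.00665). Of 10 Schwann cell and melanocyte markers 4 rose and 2 fell (4 higher and 3 lower when adjusted over the list alone; camera adjusted p = 0.364). Here too fry called a rise (adjusted p = 0.0162). Gpr37l1 (4.01 ± 2.76 to 107 ± 19.9), Mag (2.87 ± 0.965 to 53.5 ± 10.1), Ednrb (24.2 ± 4.58 to 277 ± 76.3) and Mbp (915 to 1181) rose, and Kit (519 to 215) and Sox10 (4556 to 3391) fell. Mbp lost its call without Normal replicate 1 or 2 or PVR replicate 1 or 3, and Sox10 without Normal replicate 2 or PVR replicate 2. Of 9 lens, corneal and ciliary epithelium markers 1 rose, Mab21l1 (426 ± 42.1 to 665 ± 72.8), and 0 fell (1 and 0 when adjusted over the list alone; camera adjusted p = 0.986), with a median log2 change of -0.31 although camera pointed up. Without Normal replicate 1, 2 or 3 or PVR replicate 2 or 3, 2 members rose, and without any single library other than Normal replicate 1, 1 fell. Only 3 of 8 listed erythroid genes passed the filter, and all 3 fell. They were the haemoglobin genes Hba-a1 (119 ± 47.7 to 3.48 ± 3.30) and Hbb-bs (137 ± 63.4 to 6.96 ± 4.89), which have near-identical copies, and Alas2 (29.7 to 12.8). The Alas2 call was lost without any single library. Genes near 0 in PVR pass the filter only if higher in Normal, so the filter partly sets this count. Mitochondrially encoded genes were not analysed here.

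Of the 32 lists with at least 5 tested genes, camera called 18 higher and 4 lower with its preset correlation and 0 with an estimated correlation, for which the smallest adjusted p was 0.276. The rotation test fry, which asks whether the genes of a list move on balance in one direction, called 19 higher and 2 lower. In the cytokine, interferon, unfolded protein, ribosomal, neutrophil and lymphocyte lists, where 0 members fell by limma, 0 also fell at an unadjusted p under 0.05, with edgeR and with DESeq2, unlike the 2 of the pericyte and smooth muscle list at an unadjusted p. In the oxidative phosphorylation list, where 0 rose, 1 member was higher at an unadjusted p under 0.05 and 0 rose with edgeR or DESeq2.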

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

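EdgeR with TMM, TMM scaling in limma, pseudocounts 8 and 0.25 and the joint removal of Normal replicate 2 and PVR replicate 3 were chosen after seeing the data, the other alternatives before. The 4858 changed genes became 4698 to 5002 under other tools, scalings, filters and pseudocounts, 5328 with the replicate number as a block (4738 shared), 4014 with replicates 1 and 2 only and 1481 (1232 higher, 249 lower) when tested against a 1.5-fold change, a stricter question by construction. Leaving out 1 library gave 3614 to 4870 genes (2193 to 2844 higher, 1307 to 2026 lower), with fewer samples in the fit, and 2986 genes were called in the fit of all 6 libraries and in all 6 of these. None of the 4858 was called with the opposite sign when a library was left out. Scaling to library totals gave 2538 higher and 2464 lower genes, with a median log2 change of -0.0896 against -0.0165, and turned Traf6 to -0.0140, neither value being called. Camera called 18 higher and 4 lower lists, 17 to 20 and 3 to 4 when 1 library was left out, 2 lower with replicates 1 and 2 only, 0 and 0 with an estimated correlation, which allows for genes of a list moving together, and 2 lower with fry. The first principal component held 73.9% of the variance when all genes passing the filter were used. Of the 214 named genes 200 were called, and 170 of these stayed past the threshold in every alternative other than the 1.5-fold test. The block changed the calls of Dkk3, Cd163, Il1b, Tnf, Emcn (0.025), Ly6c1 (0.021) and Prdx6 (0.047) and moved 4 list counts of higher or lower members past 1.5-fold, and changed no other call among named genes and lists. Of the counts of list members, 1221 were within 1.5 times the reported count and 179 were not. The cause of these shifts was not tested except where the construction shows it. At this depth genes such as Tnfsf11 with 19 reads in all could not be tested. The simulation missed most 1.5-fold changes, but it changed only 200 genes. Its adjusted threshold was therefore stricter than that of the data, and the share of such changes missed here is not known.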

Other observations

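The genes in this paragraph were chosen after their values were seen, so they show no change of a group of genes. Trf, which encodes the iron carrier transferrin, rose from 337118 ± 21391 to 1000940.0 ± 104257 and reached 5.75% of all normalised counts in PVR, against 2.04% in Normal. Tfrc, the transferrin receptor gene, fell from 1413 ± 84.9 to 414 ± 37.3 (log2 change -1.77, limma adjusted p = 1.98e-05), and the ferritin genes Fth1 (14014 ± 926 to 29625 ± 6975) and Ftl1 (11979 ± 1019 to 22575 ± 3578) rose, as did Hmox1 and Lcn2. The nicotinic receptor genes Chrna3 (chromosome 9, 55010111 to 55026562) and Chrnb4 (chromosome 9, 55028154 to 55048779), neighbours on the same strand, rose from 12.2 ± 5.53 to 297 ± 57.7 and from 517 to 5112. Map1a (544 to 2584), Tubb4a (147 to 1285) and Aplp1 (2023 to 11669) also rose. Arg1, an arginase gene used as a marker of some activated macrophages, rose from 4.08 ± 1.22 to 853 ± 413.

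Normal replicate 2 held transcripts at far higher levels than the other 2 Normal libraries, and the genes given here were chosen after their values were seen. Gpx3 was at 5839 normalised counts there against 59.8 and 142.3, Krt5 at 1550.3 against 0 and 0.9, and Penk at 1587 against 6.2 and 22.7, in the order of replicates 1 and 3.

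All tests in the paragraphs that follow were chosen after the results were seen. Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave as many as 4858 genes, and the highest of the other 9 was 0. Each of those 9 sets Normal and PVR libraries together in both arms, so the difference between them counts as spread. A count of 0 there follows from that design and is no support for the real count. For lists, 3 of the 10 splits called at least the real 22, the highest other being 25, among them a split that parts each numbered pair as the real one does. With 10 splits no share under 0.05 can be reached. Of the 3 other splits that part every pair, lists called were 17, 25 and 12 and genes called by limma 0.

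Macrophage and neutrophil markers rose with PVR, and macrophages in the PVR preparations are a candidate explanation. That 92.3% of the 26 macrophage markers were called higher is the pattern itself, so it does not decide for that explanation. Of the 26, 6 had at least 100 normalised counts in Normal and 0 are in another list, and Csf1r stood at 10038 there and fell. A smaller share of RPE cells that raised every other cell type alike is argued against, because the upper quartile of the endothelial log2 changes was 1.10 and the lower quartile of the macrophage changes 3.85. With each library left out in turn, the endothelial quartile was at most 1.44 (without Normal replicate 2) and the macrophage quartile at least 3.54 (without PVR replicate 1). In PVR replicates 1 to 3 Lyz2 stood at 32209, 53474 and 16984 and Rpe65 at 28403, 28578 and 38343, and the PVR mean of C1qa was 3121. Whether RPE cells themselves took up some of these transcripts or expressed them was not tested, and no sort or gate is described in the labels.

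PVR replicate 3 lay nearer to Normal than the other PVR libraries. Genes that fell reached a median 0.734 of the change seen in the other 2 PVR libraries, against at least 1.04 for PVR replicates 1 and 2 when each was left out. The values over 1 follow in part from the low PVR replicate 3 in their reference. The genes were called anew without each library (1533, 1434 and 2026 that fell without PVR replicates 1, 2 and 3). Fewer macrophages alone may explain this and stay open, since they would also dilute RPE transcripts less. A single share of cells in the Normal state would give genes that fell and macrophage markers (0.387) the same median share, and these differed by 0.347. Their intervals were apart but resample genes of 1 library, which do not move independently. PVR replicate 2 also showed a gap (1.11 for genes that fell, 1.6 for macrophage markers). PVR replicate 3 is part of the reference for that gap, so the gap is no independent check. The difference of 0.347 rests on 1 library and does not decide against that explanation. In PVR replicate 3 matrix genes reached 0.589, visual cycle genes 0.802 and cytokines 0.345. A milder or earlier disease state together with fewer immune cells may remain, as may a difference in deposit or handling of the replicates numbered 3, and neither was tested.

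Tnfrsf11a and Nfatc1 rose together with macrophage markers, and transcripts brought by macrophages are a candidate explanation, since both are expressed in that lineage. Tnfrsf11a lay within the macrophage markers' 10th to 90th percentile of change in 3 of the 3 PVR libraries, each left out in turn, and Nfatc1 in 1 of 3. The counting intervals overlapped that range in each library for both genes, and overlapped the range of other risen genes as well, so that macrophage transcripts and a rise within RPE cells cannot be told apart for either gene. The few reads of Tnfrsf11a and a change under 2-fold for Nfatc1 keep this open, and cell-resolved counts would be needed.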
